A study of Mus musculus with 6 samples.

How the data were processed

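RNA was measured in 6 mouse libraries of sorted GFP-positive acinar cells, 300 cells per library, prepared by a modified Smart-seq2 protocol with 12 cycles of preamplification. Per the labels, the authors trimmed reads with Trim Galore 0.6.4, checked them with FastQC, aligned them with STAR 2.7.9a to build mm10 and counted them with featureCounts, with SAMtools in between. The deposited values are raw counts per gene symbol, whole numbers with no normalization. The deposited Length column is another quantity, the length in bp of the counted interval, and it equals end minus start plus 1 for all 55253 symbols with 1 interval, so counts cover whole gene spans with introns. The annotation release, the strand setting and the handling of reads with several alignments are not stated. The labels give the molecule as genomic DNA although the title and protocol describe RNA-seq.

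Each file holds 55367 symbols, of which 55141 could be given an exon length from the GENCODE mouse annotation by symbol or coordinates, with 99.9967% of the counts. TPM was computed as counts per kb of exon length, scaled to a total of all genes including ribosomal RNA, and levels were taken as log2(TPM + 1). Because counts include introns, TPM here overstates genes with long introns where unspliced RNA or DNA was sequenced. A background was therefore estimated in each library as counts per Mb over 1711 olfactory and vomeronasal receptor genes spanning 12.9 Mb, with 7873 counts in total, and multiplied by each gene's span to give its expected background. Of 743 protein-coding genes wholly inside a gene on the opposite strand, 730 had no counts in any library, which points to overlapped reads being dropped. The listed genes Iapp, Neurod1, Sycn, Cela2a, Itgam, Igkc, Ms4a1, Ccl2, Alas2 and Xist had no counts and lie almost wholly inside the spans of other genes, so no absence is read from them. Total counts of 4670819 to 7072270 per library set the precision, and shares of single libraries carry exact Clopper-Pearson 95% intervals.

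The 28 gene lists, the 10 pairs of lists, the rule for named genes and the tests were fixed before the data were examined. The lists cover acinar enzymes, acinar transcription factors, pancreatic endoderm transcription factors, acinar receptors and exocytosis, ER secretory and unfolded protein response genes, ductal, metaplasia and injury, Reg and inflammatory, endocrine, fibroblast and stellate, endothelial, myeloid, lymphoid, erythroid, adipocyte and mesothelial, Schwann, sex-linked, mitochondrially encoded, ribosomal protein (by the name pattern Rpl or Rps, which also takes S6 kinase genes and Rps19bp1), proliferation, immediate early and dissociation, AP-1, Klf, EGFR with RAS and MAPK, and YAP with Notch genes, and remodelling ATPases, ISWI partners and BAF subunits. Genes to be named were the 20 most abundant protein-coding genes, the 4 highest members and the lowest member of each list, every remodelling ATPase within 1 log2 unit of Smarca5 or above it with Smarca1, Smarca5 and Klf5, between the sets the 10 largest rises and falls with adjusted p under 0.05, mean TPM of 5 or more and no overlap, and the 5 most variable protein-coding genes with mean TPM of 20 or more. The rule between the sets took no gene, and genes named there were chosen after their values were seen.

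List pairs, ATPases against Smarca5 and Klf genes against Klf5 were tested within libraries with the exact two-sided sign-flip test over 64 sign patterns, adjusted by Benjamini-Hochberg within each family at a threshold of 0.05. The numbers in the deposited names place replicates 1 to 3 in set A and replicates 4 to 6 in set B, which was treated as a possible batch and not as a study group. The sets were compared with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test), with camera of limma 3.58.1 at a preset correlation of 0.01 on log CPM (counts scaled to the library total) with a prior count of 2, and with fry and camera with an estimated correlation beside it. Lists with too few genes past the filter left 22 lists tested, without the myeloid, lymphoid, erythroid, adipocyte, Schwann and sex-linked lists. Similarity was the mean Spearman correlation within minus between sets over the 10 splits into 3 and 3. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.

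The tests were tested on simulated data. Of 100 simulated genes changed 4-fold between the sets edgeR recovered 63%, and of 100 changed 2-fold 8%, with 6.58% of calls being unchanged genes. Both simulated sets had the same spread, whereas the real coefficient of variation was 0.141 in set A and 0.449 in set B, so these shares may differ in the real data. With the proliferation list raised 2-fold, camera gave it an adjusted p of 6.7e-04 and called 0 other lists. The simulated genes varied independently, whereas the estimated correlation in the real data reached 0.871 for the enzyme list. The simulation therefore does not show how often camera calls correlated lists by error. The exact sign-flip test gave p under 0.05 in 2.9% of 2000 draws with no difference and in 99.75% with a difference of 3 SD. These p-values were unadjusted, so the shares do not apply to the adjusted tests.

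Alternatives were CPM in place of TPM, a pseudocount of 0.1, other thresholds for detection, the enzyme genes left out of the total, members with mean TPM of 1 or more, medians of members, DESeq2 size factors and the DESeq2 test, other filters on low counts, camera with an estimated correlation, and leaving out each replicate in turn. Gene span lengths, background subtraction, ribosomal RNA or overlapped genes left out, genes with background under 20%, the Rpl and Rps list without S6 kinase genes and Rps19bp1, and the limma test of within-library differences were added after the data were seen. Further lists of mitosis genes, islet genes other than hormones, ATF4 targets and long brain-type genes were written for tests in the closing part. No library was left out of the values given first.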

Results

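The data are RNA-seq libraries of mouse pancreatic acinar cells, the exocrine cells that make and release digestive enzymes, and the series states that their expression pattern was the object of study. All 6 libraries belonged to 1 group, from untreated mice with the genotype Pdx1-Cre; Klf5-mCherry-CreERT2, and each was made from 300 sorted GFP-positive cells, although the genotype label names no GFP reporter. Total counts were 7053088, 5552288, 6367427, 6805339, 4670819 and 7072270 in replicates 1 to 6. A number in the library names, whose meaning is not given, parts replicates 1 to 3, called set A, from replicates 4 to 6, called set B. Nothing in the labels says whether the libraries came from separate animals, so p-values of tests across libraries measure only the spread between these samples. Camera with a preset correlation sets the genes of a list against the other genes. Its p-values rest on the spread between genes and do not measure that between libraries.

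The listed digestive enzyme genes took from 12.3% of the counts in replicate 5 (exact Clopper-Pearson 95% interval 12.3% to 12.4%) to 46.3% in replicate 1 (46.3% to 46.3%), with a mean of 29.4% ± 13.8 (SD, n = 6). Ribosomal RNA genes took 50.4% ± 10.2. Olfactory and vomeronasal receptor genes, which serve as a measure of background here, had 27.9 to 116 counts per Mb of gene span in 5 libraries and 341 in replicate 5. A count of 0 in a library allows up to 3 counts, which is 0.424 to 0.642 CPM (counts scaled to the library total), and intervals and floors of this kind cover counting error only.

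**Figure D1:**
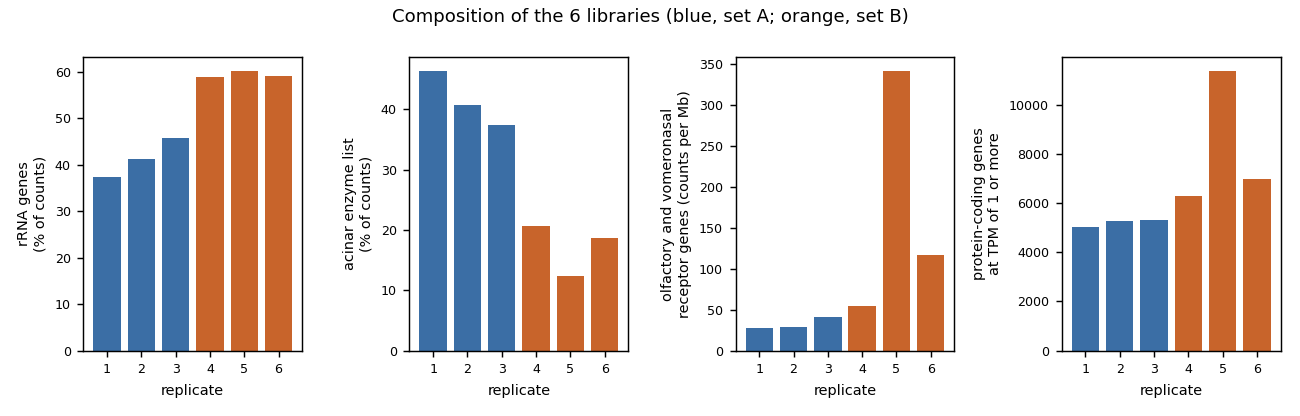
Composition of each library by replicate: percent of counts in ribosomal RNA genes, percent in the acinar enzyme list, background in counts per Mb over receptor genes, and number of protein-coding genes at a TPM of 1 or more. Blue bars are set A and orange bars set B; ribosomal RNA lies between 37.4% and 45.8% in set A and between 58.9% and 60.1% in set B.

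Genes of digestive secretion led the profile. The chymotrypsinogen gene Ctrb1 (chromosome 8, 111686519 to 111691010, build mm10) reached 84808 ± 30660.3 TPM (transcripts scaled by length and library total; SD, n = 6), the trypsinogen gene Prss2 71070.2 ± 32735 TPM and the pancreatic colipase gene Clps 70817 ± 32896 TPM. They were followed by the trypsinogen-like gene Try4 at 37601 ± 4737, the chymotrypsin-like gene Ctrl at 24417 ± 12804, the elastase gene Cela1 at 23134 ± 7135 and the lipase gene Pnlip at 19714 ± 7296 TPM. Of the 20 most abundant protein-coding genes, 15 were in the acinar enzyme list, the remaining members being Rnase1, Try5, Cpa1, Cela3b, Cel, Zg16, Cpb1 and Pnliprp1, and those 20 genes held 86.2% ± 6.71 of all protein-coding TPM. The 5 outside it were Reg1, a secreted lectin of acinar cells, at 17424.5 ± 4192 TPM, 2210010C04Rik at 14745 ± 5655, Gphn at 8006 ± 4287, Lars2 at 7984 ± 5363 and Gm10800 at 6069 ± 11007 TPM. The last 3 need caution, because Gm10800 resembles satellite repeats, and the shares of Lars2 and Gphn moved with the share of ribosomal RNA. Lars2 took 2.17% ± 0.552 of the counts in set A and 6.74% ± 0.821 in set B (SD, n = 3 each), and Gphn 0.95% ± 0.280 and 2.13% ± 0.267. The 5 most variable abundant genes included the insulin genes Ins2, at 5.49 to 1324 TPM across libraries, and Ins1, at 2.51 to 729 TPM, with Chl1 at 2.68 to 518, Gm10945 at 0 to 202 and Gm10801 at 196 to 19369 TPM.

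Of 21950 protein-coding nuclear genes, 3762 had a TPM of 1 or more in all 6 libraries, 439 had 10 or more, 64 had 100 or more and 24 had 1000 or more. The number at 1 TPM or more per library was 5006 to 6987 outside replicate 5 and 11358 in replicate 5. With whole gene lengths in place of exon lengths, a scale chosen after the values were seen, 1140 genes reached 1 TPM in every library.

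The acinar identity lists stood highest among the cell type lists. The mean log2(TPM + 1) over the acinar enzyme list was 9.52 ± 0.37 (SD, n = 6), and 32 of its 36 genes had a mean of 1 TPM or more. The acinar transcription factors averaged 3.57 ± 0.12, with Xbp1, a driver of secretory capacity, at 42.0 ± 14.6 TPM, Bhlha15 (Mist1) at 32.0 ± 6.50, Rbpjl at 24.8 ± 7.26, Ptf1a at 11.6 ± 2.67 and Gata6 lowest at 1.21 ± 0.587. Genes of protein folding in the endoplasmic reticulum (ER) and the unfolded protein response averaged 4.38 ± 0.16, led by the disulfide isomerase genes Pdia2 at 934 ± 357 and P4hb at 265 ± 31.7 TPM. In the list of receptors and exocytosis genes, at 2.31 ± 0.11, the cholecystokinin receptor gene Cckar had 62.8 ± 7.10 TPM, the gap junction gene Gjb1 21.5 ± 1.86, the muscarinic receptor gene Chrm3 16.6 ± 4.18 and Rab3d 15.8 ± 1.69. Amy2b, annotated as an unprocessed pseudogene of the amylase family, had 370 ± 150 TPM and Amy2a5 17.6 ± 2.92, and how reads shared by near-identical copies were counted is not stated. Sycn and Cela2a had no counts, but their exons lie inside the spans of other genes. Of 743 protein-coding genes wholly inside a gene of the other strand 98.3% had no counts in any library, against 9.28% of 14252 genes free of overlap.

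Part of the injury, metaplasia and early-response genes was measurable in these sorted cells of untreated mice. A mean of 1 TPM or more was reached by 13 of 20 metaplasia and injury genes and 7 of 16 Reg and inflammatory genes. Among the immediate early and dissociation genes, called immediate early genes below, 15 of 19 reached it. Counts were over 3 times background in all 6 libraries for 10, 7 and 15 genes of these lists. Tff2, a secreted trefoil peptide, had 4035 ± 400 TPM, Clu 128 ± 35.7, S100a11 16.2 ± 8.52 and Cd44 10.6 ± 2.76, and the metaplasia and injury list averaged 2.18 ± 0.36. The Reg and inflammatory list averaged 2.84 ± 0.18, with Reg2 at 272 ± 119, Reg3d at 197 ± 69.4 and Reg3b at 58.4 ± 12.0 TPM, while Saa3 had no counts. Immediate early genes averaged 2.51 ± 0.23, with Fos at 36.8 ± 10.9, Ier2 at 21 ± 4.70, Btg2 at 18.6 ± 7.41 and Jun at 17.2 ± 3.08 TPM, and the AP-1 list, which shares Fos and Jun, averaged 2.11 ± 0.14. All cells were sorted, so a response of these genes to dissociation cannot be told apart from their level in the tissue. The proliferation list averaged 0.65 ± 0.38, with Pcna highest at 1.94 ± 0.70 TPM and Aurkb lowest at 0.158 ± 0.121.

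Lists of other cell types were lower. The ductal list averaged 1.98 ± 0.34, led by Spp1 at 51.5 ± 40.6 and Muc1 at 28.5 ± 8.33 TPM, with the duct keratin gene Krt19 at 5.05 ± 2.30. The endocrine list averaged 1.11 ± 0.50 but was uneven. Its highest genes were Ins2, with a mean of 362 TPM (5.49 to 1324 across libraries), and Ins1, with a mean of 160 TPM (2.51 to 729). Glucagon (Gcg) had 29.3 ± 67.0 TPM, an SD above its mean. The pancreatic endoderm transcription factors averaged 0.89 ± 0.23, led by Foxa3 at 5.59 ± 1.02. Fibroblast and stellate genes averaged 0.71 ± 0.40, led by Sparc at 4.36 ± 2.80 TPM, endothelial genes 0.54 ± 0.44, myeloid genes 0.52 ± 0.21, erythroid genes 0.42 ± 0.77, adipocyte and mesothelial genes 0.38 ± 0.40, Schwann cell genes 0.26 ± 0.28, lymphoid genes 0.23 ± 0.22 and sex-linked genes 0.08 ± 0.06. Expected background equalled 94.0% of the counts of Tek and 67.6% of those of Pecam1, the highest endothelial genes. The mitochondrially encoded genes averaged 6.45 ± 0.14. Genes with names in Rpl or Rps averaged 4.50 ± 0.10, and 4.92 ± 0.10 without 11 genes of S6 kinases and Rps19bp1 that the name pattern also took. The signalling and chromatin lists lay close together, with EGFR, RAS and MAPK genes at 1.20 ± 0.16, YAP and Notch genes at 1.18 ± 0.21, Klf genes at 1.26 ± 0.14, partners of the ISWI remodellers at 1.18 ± 0.21, BAF subunits at 1.11 ± 0.20 and remodelling ATPases at 0.89 ± 0.26.

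**Figure D2:**
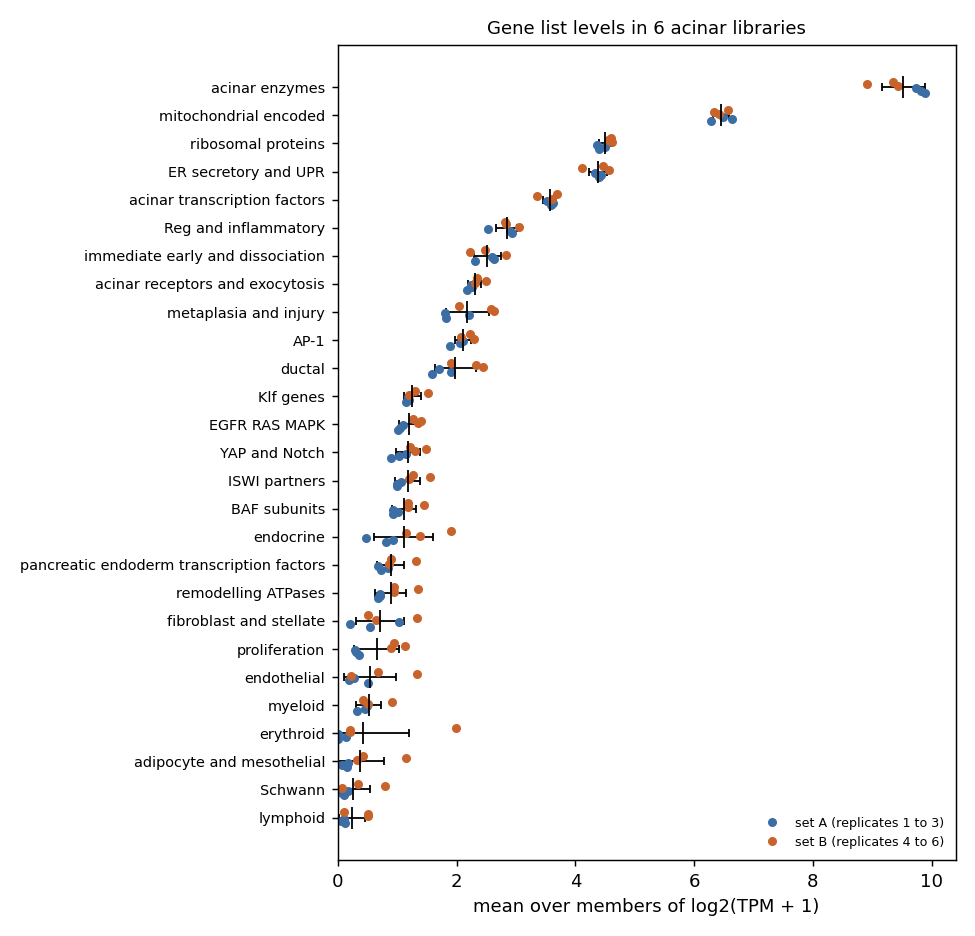
Mean of log2(TPM + 1) over the members of each gene list (horizontal axis), with 1 point per library, blue for set A and orange for set B; the tick is the mean of 6 libraries and the bar its SD. The acinar enzyme list lies highest at 9.52 and the sex-linked list is not drawn.

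Paired within each library, the acinar lists stood above the lists they were set against. The acinar transcription factors exceeded the ductal list by 1.58 ± 0.39 log2 units (SD, n = 6) and the pancreatic endoderm transcription factors by 2.67 ± 0.32, each in 6 of 6 libraries. The enzyme list exceeded the ER list by 5.14 ± 0.31, the immediate early list exceeded the proliferation list by 1.86 ± 0.48, and the myeloid list exceeded the lymphoid list by 0.28 ± 0.16, also in 6 of 6. With overlapped members left out, a setting chosen after the values were seen, the enzyme minus ER difference was 5.79. The ductal minus metaplasia difference was -0.20 ± 0.08, with the metaplasia list higher in 6 of 6, but it took the opposite sign without length scaling (0.10), with a pseudocount of 0.1 (0.09) and with the median of members (0.47, past the exact test at an adjusted p of 0.039). The ductal list exceeded the endocrine list by 0.87 ± 0.46 and was exceeded by the receptor list by 0.32 ± 0.27, each in 5 of 6 libraries. By gene span lengths, a scale chosen after the values were seen, ductal minus endocrine was 0.43, receptors minus ductal 0.20 and myeloid minus lymphoid 0.12. The ISWI minus BAF difference was 0.06 ± 0.06, higher in 5 of 6, and the fibroblast minus endothelial difference 0.17 ± 0.35, higher in 4 of 6, or 0.055 without replicate 3.

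None of the 10 pairs passed the exact two-sided sign-flip test after adjustment, since 6 libraries allow no exact p under 0.031, which the 6 pairs with 1 direction in every library reached, and the smallest adjusted exact p was 0.052. The limma test of the same differences, chosen after the values were seen, passed 8 of the 10. Kept to members with a mean of 1 TPM or more, the ISWI minus BAF difference was -0.22, past the exact test in that direction (adjusted exact p = 0.045), and the ductal minus endocrine difference -0.42.

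Smarca5, the ISWI-type remodelling ATPase in the series title, was measured at a low level and set against 31 other remodelling ATPases in the same libraries. It had 1.37 ± 0.409 TPM (SD, n = 6; chromosome 8, 80698507 to 80739497), from 21 to 51 counts per library, of which expected background made up 11.8%. Smarca4, the BRG1 ATPase of BAF complexes, had 3.35 ± 1.52 TPM and exceeded Smarca5 by 0.81 ± 0.43 log2 units in 6 of 6 libraries, although by gene span lengths the difference was -0.03. Chd4, the ATPase of the NuRD complex, had 3.03 ± 0.696 TPM and exceeded Smarca5 by 0.77 ± 0.18, also in 6 of 6. Smarca1, the other ISWI ATPase gene, had 0.740 ± 1.15 TPM and a difference of -0.61 ± 0.63, lower in 5 of 6, which became -1.59 with a pseudocount of 0.1. Expected background made up 72.8% of its counts.

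Averaged over the libraries, 5 of the 31 genes were above Smarca5 and 26 below it. Distances below it are compressed by the pseudocount of 1, which limits how far under Smarca5 even a gene with no counts can lie, so the direction says more than the size. Ercc6l2 at 0.333 TPM and Rad54l at 0.196 TPM, for example, gave -0.82 and -0.98. Ino80 (1.85 ± 0.814 TPM), Chd9 (1.64 ± 0.50) and Chd6 (1.55 ± 0.618) were slightly above it, and Btaf1, Ep400, Atrx, Chd1, Chd7, Chd2, Smarca2 and Chd1l slightly below, with differences from 0.24 to -0.13. Lower in 6 of 6 were 14 genes, namely Hltf, Smarcad1, Smarcal1, Shprh, Rad54l2, Chd3, Rad54b, Ercc6l2, Chd8, Chd5, Rad54l, Ttf2, Ercc6l and, at -1.05 ± 0.24, Srcap, whose exons lie mostly inside another gene. Zranb3, Ercc6 and Hells were lower in 5 of 6. Expected background made up 20% or more of the counts of 23 of the 31 genes.

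No ATPase passed the exact sign-flip test after adjustment, where 16 genes had the smallest possible exact p of 0.031 and the smallest adjusted exact p was 0.061. The limma test, chosen after the values were seen, passed 2 genes above and 17 below Smarca5. Without length scaling 12 genes averaged above Smarca5, and without replicate 6 there were 8.

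Klf5, the transcription factor gene named in the genotype, was set against the other 16 Klf genes. It had 0.784 ± 0.123 TPM (SD, n = 6; chromosome 14, 99298691 to 99315036), from 9 to 16 counts per library, with 12.2% of them expected as background. Klf15 had 13.9 ± 4.42 TPM and exceeded Klf5 by 3.01 ± 0.50 log2 units, Klf9 had 9.71 ± 1.31 and exceeded it by 2.58 ± 0.16, Klf6 had 7.53 ± 1.74 and exceeded it by 2.23 ± 0.31, and Klf13 had 3.32 ± 0.641 and exceeded it by 1.27 ± 0.20, each in 6 of 6 libraries. By gene span lengths, a scale chosen after the values were seen, the differences of Klf15, Klf9 and Klf13 were 1.98, 1.37 and 0.31, while that of Klf6 was 2.22, and with CPM that of Klf13 was 2.16. Klf12 exceeded Klf5 by 0.93 ± 0.74 in 6 of 6, but background made up 71.5% of its counts and the difference was -0.36 by gene span lengths and 0.091 after background subtraction. Klf4, known with Klf5 from epithelial plasticity, gave -0.37 ± 0.24, and Klf16, Klf1, Klf17 and Klf14 gave -0.39 to -0.78, each lower in 6 of 6. These sizes are set largely by the pseudocount of 1, since Klf5 itself is under 1 TPM and Klf14 had 2 counts in all libraries together.

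In this family 10 of the 16 genes had the smallest possible exact p of 0.031 and an adjusted exact p of 0.05, which is not under the threshold, so none passed. The limma test, chosen after the values were seen, passed 5 genes above and 5 below Klf5. The counts of Klf5 do not separate the modified allele from the normal allele.

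**Figure D3:**
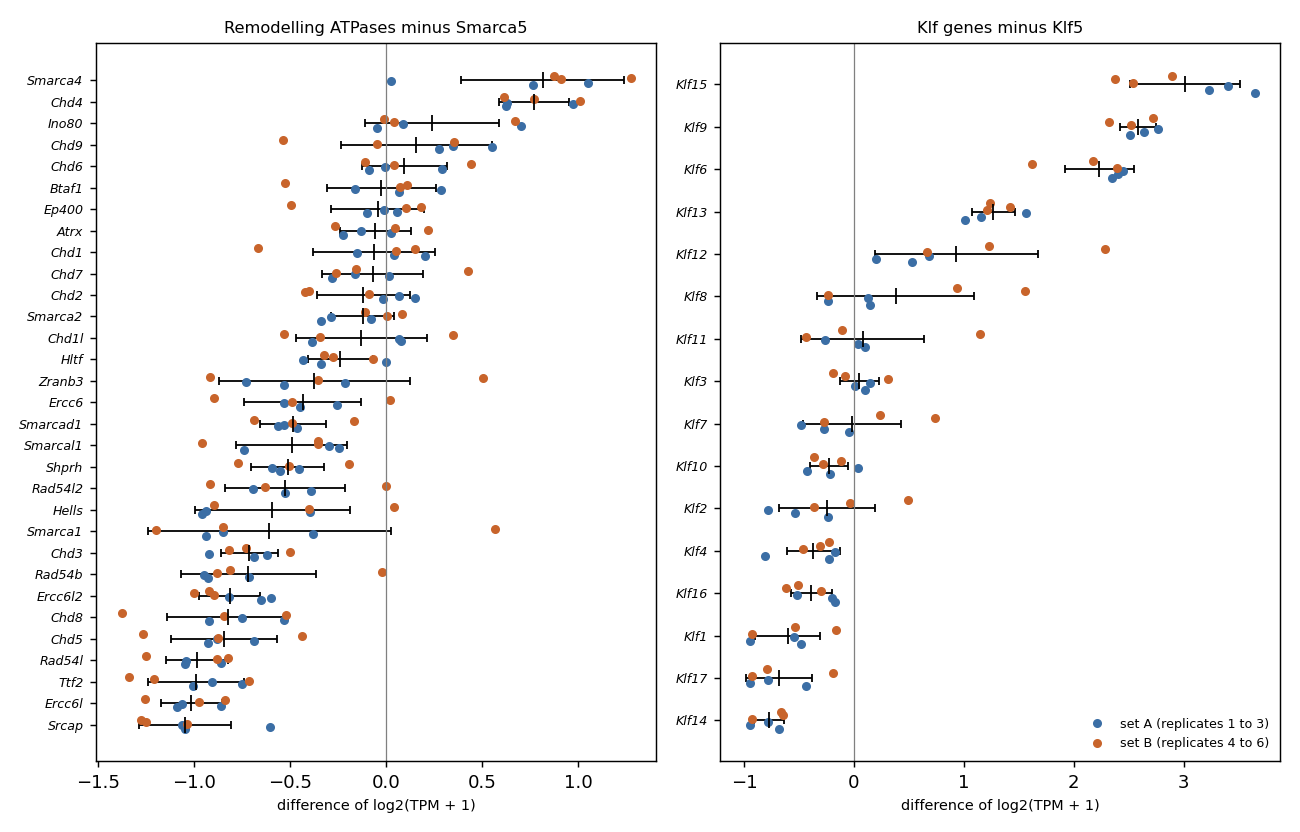
Within-library difference of log2(TPM + 1) of each remodelling ATPase gene from Smarca5 (left) and of each Klf gene from Klf5 (right), with 1 point per library, blue for set A and orange for set B; ticks are means of 6 libraries and bars their SD. Smarca4, at 0.81, and Chd4, at 0.77, lie above Smarca5 in 6 of 6 libraries, and Klf15 lies highest above Klf5 at 3.01.

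The 2 sets of libraries were compared as a possible batch, since all labels are the same. The mitotic topoisomerase gene Top2a (chromosome 11, 98992943 to 99024189) was higher in set B by 4.71 log2 units (SE 0.47, n = 3 and 3, edgeR adjusted p = 0.022). It had 4 counts over set A and 125 over set B, a ratio of 46.1 per count outside ribosomal RNA (exact 95% interval 17.5 to 172). The mitosis genes Mki67, with 17 and 143 counts (ratio 12.4, 7.48 to 21.9), and Cdk1, with 1 and 65 counts (ratio 95.8, 16.6 to 3841), did not pass over all genes. These intervals pool the reads of each set and leave out the spread between libraries. Expected background equalled 75.8% of the set A counts of Top2a and 173% of those of Cdk1. Their ratios thus set set B largely against background, and the size of the fold is not measured. Digestive enzyme genes lay lower in set B, with log2 differences of -1.90 ± 0.45 (SE) for Ctrl, -1.47 ± 0.38 for Pnlip and -1.41 ± 0.42 for Ctrb1, which did not pass over all genes either. Insulin transcripts lay higher in set B, by 5.63 ± 1.27 for Ins2 and 5.08 ± 1.29 for Ins1, without passing, and that excess was in replicates 4 and 6 and not in replicate 5.

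These genes were named after their values were seen, because Top2a averages under 5 TPM and the rule for named genes took none. By edgeR's quasi-likelihood test 1 gene was higher and 0 lower in set B among 8723 tested, with 2258 at an unadjusted p under 0.05, and DESeq2 called 794 higher and 227 lower. The edgeR counts were 1656 higher and 561 lower without replicate 4, 366 and 369 without replicate 5, and 0 without replicate 1, 2, 3 or 6, while without a filter on low counts they were 790 and 203.

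By gene list, camera with a preset correlation called 6 of 22 fixed lists, and none of the 6 calls held after adjustment with an estimated correlation. The adjusted p of 0.72 that recurs below is a tied value. Under it the unadjusted p by camera with an estimated correlation ran from 0.088 (endocrine) to 0.51 (Rpl and Rps) among the called lists. The acinar enzyme list was lower in set B (adjusted p = 1.4e-12, or 0.72 with the estimated correlation of 0.871, median log2 difference -1.26). Adjusted over the list alone 21 of its 32 tested genes were lower and 1, Prss1 at 1.02 ± 0.32 (SE), was higher, against 0 over all genes. Relative to other genes the list lay at -1.27 log2 units, and in settings chosen after the values were seen at -0.75 among low-background genes and -0.59 after background subtraction. Ribosomal RNA took 41.5% ± 4.24 of counts in set A and 59.4% ± 0.640 in set B, and background was 32.3 ± 7.08 and 171 ± 151 counts per Mb (SD, n = 3 each). The proliferation list was higher in set B (adjusted p = 3.1e-04, or 0.27 with an estimated correlation, median 1.56), with 4 of 9 genes higher adjusted over the list alone, namely Top2a, Cdk1, Mki67 and Aurka, and 1 over all genes. Its estimated correlation was -0.013, not above the preset 0.01, and its unadjusted p by camera with that estimate was 0.012. The endocrine list was higher (adjusted p = 0.0047, or 0.72 with an estimated correlation, median 3.2), with 4 of 5 genes higher adjusted over the list alone, namely Pcsk2, Ins2, Chga and Ins1, and 0 over all genes. Relative to other genes the endocrine list lay 2.58 log2 units higher. The call was lost without replicate 6 (1.75, adjusted p = 0.083 by camera) and at a mean count of 50 or more (2.31, 0.26). It held without replicate 3 (1.69). Background is expected to supply 91.7% of the set B counts of Pcsk2.

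Genes of the ER and the unfolded protein response were lower in set B (adjusted p = 9.96e-04, or 0.72 with an estimated correlation, median -0.43), where 1 of 32 genes, Herpud1 at -1.61 ± 0.36 (SE), was lower adjusted over the list alone and 0 over all genes. Relative to other genes the ER list lay at -0.61 log2 units, and at -0.98 without replicate 4. The call was lost without replicate 5 (-0.28, adjusted p = 0.11 by camera), at a mean count of 50 or more (-0.43, 0.081) and, in settings chosen after the values were seen, among low-background genes (-0.11, 0.68) and after background subtraction (0.0024, 0.84). By TPM the sets hardly differed, with a mean log2(TPM + 1) of the ER list of 4.39 ± 0.06 in set A and 4.38 ± 0.24 in set B (SD, n = 3 each). TPM is scaled to a total that includes the enzyme genes, which lay lower in set B. A gene's TPM can therefore rise there while its counts fall. Ssr3, for example, averaged 259 counts in set A and 219 in set B, but 16.2 and 17.4 TPM. The same limit applies to TPM of the immediate early and the Rpl and Rps lists.

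Immediate early genes were lower as a list (adjusted p = 0.030, or 0.72 with an estimated correlation, median -0.49), with 0 members called over all genes or adjusted over the list alone. Relative to other genes they lay at -0.66 log2 units, and at -1.09 without replicate 4. That call was lost without replicate 2 (-0.66, adjusted p = 0.060 by camera), replicate 3 (-0.66, 0.073) or replicate 5 (-0.20, 0.31), at a mean count of 50 or more (-0.75, 0.062), among low-background genes (-0.18, 0.50) and after background subtraction (-0.11, 0.31). On the TPM scale the immediate early list had the same level in the sets, 2.51 ± 0.18 in set A and 2.51 ± 0.31 in set B (SD, n = 3 each).

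Genes with names in Rpl or Rps were lower as a list (adjusted p = 0.0022, or 0.72 with an estimated correlation, median -0.30), again with 0 members called. Its 81 tested genes included 9 that are not ribosomal proteins, 8 of the S6 kinase kind and Rps19bp1. Without such genes, left out after the values were seen, the list lay at -0.51 log2 units relative to other genes against -0.39 with them. It lay at -0.61 without replicate 3 and -0.70 without replicate 4. The call was lost without replicate 5 (-0.18, adjusted p = 0.18 by camera), at a mean count of 50 or more (-0.31, 0.11) and among low-background genes (0.022, 0.65). The list turned to higher in set B after background subtraction (0.24, 0.015). Its mean log2(TPM + 1) over all 101 members was 4.42 ± 0.07 in set A and 4.59 ± 0.03 in set B (SD, n = 3 each). The lower direction thus held on the edgeR scale and not by TPM.

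Median, mean and test direction had the same sign in each called list, and among the others they differed for the BAF subunits, with a median of -0.10, a mean of 0.07 and a test direction of higher. Fry, which tests whether a list moves in 1 direction, gave the proliferation list an adjusted p of 0.012 and the enzyme and endocrine lists 0.15, and the ER, Rpl and Rps, and immediate early lists 0.39.

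**Figure D4:**
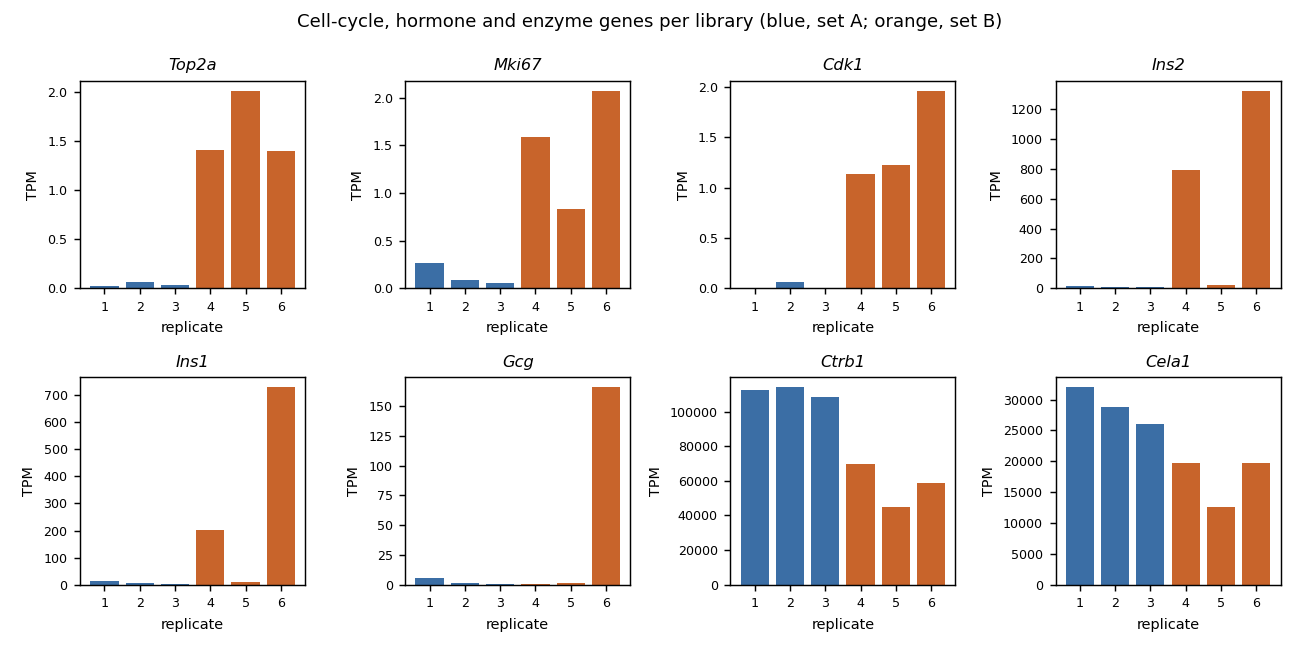
TPM of cell-cycle genes (Top2a, Mki67, Cdk1), hormone genes (Ins2, Ins1, Gcg) and enzyme genes (Ctrb1, Cela1) by replicate, with 1 bar per library, blue for set A and orange for set B. Top2a averaged 0.0406 TPM in set A and 1.61 in set B, while Ins2 reached 1324 TPM in replicate 6.

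Likeness between libraries was high within set A and uneven within set B. Across genes, which are not independent replicates, the mean Spearman rho was 0.818 within sets and 0.719 between sets, a difference of 0.099 that was the highest of the 10 splits (exact one-sided p = 0.1, the smallest that 10 splits allow). The difference was 0.045 with Pearson correlation and 0.037 over all genes with any count. The rho of replicate 5 with the set A libraries was 0.441 to 0.513, against 0.909 to 0.924 among those libraries. The mean within the set was 0.916 for set A and 0.721 for set B, the latter near the mean between sets.

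Without replicate 5, the library with the highest background, a comparison chosen after the values were seen, Ins2 (6.17 ± 0.34, SE), Ins1 (5.61) and Wfdc10 (4.51) rose in set B, at edgeR adjusted p of 0.0015 or less. The other 12 of the 15 largest rises included Lars2 (1.53), whose share moved with ribosomal RNA, the satellite-like Gm21738 (1.74) and Gm10800 (1.53), Gm10722 (1.77) and Gm10718 (1.68). They also included Gm29865, Gm11906, Gm15155 and Gm49171, whose expected background equalled 104% to 135% of their counts, and Gm33838, CT010467.2 and 2610035D17Rik. Fgf21 (-2.48), Nupr1 (-1.80) and Atf5 (-1.71), the metallothionein gene Mt1 (-2.0 ± 0.20), Dusp26 (-2.53), the neuropeptide gene Gal (-1.99), the glutathione transferase gene Gstm1 (-1.68) and the enzyme gene Ctrl (-1.59) fell, at edgeR adjusted p of 9.0e-04 or less. The other 7 of the 15 largest falls were Smim24, Serpinb1a, Tmed11, Klk1b11, Cth, Rfk and 1810018F18Rik. In that fit 22 of 32 enzyme genes were lower and 1 higher, 6 of 7 endocrine genes were higher, 4 of 11 proliferation genes were higher, and 5 of 32 ER genes were lower and 1 higher. Replicate 5 is also the set B library without the insulin excess, so leaving it out favours the rises of Ins2, Ins1 and the endocrine genes.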

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

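Most tests of the patterns in this part were chosen after the result was seen, namely those of the cell-cycle genes, of the hormone reads, of unspliced RNA in replicate 5 and of the other splits of the libraries, while the test of genomic DNA in replicate 5 was chosen before.

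Of 51 quantities examined per library, 10 had 1 library far from the other 5, and 8 of these were in replicate 5. Chance alone gives about 1 in 20 for a single quantity. The quantities are not independent, since list differences are built from list levels and several quantities can rise with background. The counts can therefore not be set against that rate. In replicate 5 the background was 341 counts per Mb against 27.9 to 116 in the others, and 11358 protein-coding genes had a TPM of 1 or more against 5006 to 6987. Its share of counts was 0.868% for Camk1d (exact 95% interval 0.860% to 0.877%) against 0.238% to 0.445%, and 1.45% for Gm10800, Gm10801 and Gm21738, which resemble satellite repeats (1.43% to 1.46%), against 0.0301% to 0.292%. List levels in replicate 5 were 1.32 for pancreatic endoderm transcription factors (others 0.68 to 0.90), 0.92 for myeloid genes (0.32 to 0.51) and 1.15 for adipocyte and mesothelial genes (0.07 to 0.42). The acinar minus endoderm transcription factor difference was 2.03 in replicate 5 against 2.75 to 2.86. In replicate 6 the erythroid list reached 1.99, against 0 to 0.21, and the ductal minus endocrine difference was -0.011, against 0.77 to 1.23.

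The background of replicate 5 covered genes that acinar cells are not known to transcribe. Unspliced RNA of expressed genes is argued against by 30 long autosomal genes of brain type, which play no part in the background measure and whose rate per Mb in replicate 5 was 2.81 times that of the next library. Genomic DNA stays open and had the values it needs, since those long genes had 0.947 times the rate of the receptor genes in replicate 5, where reads spread evenly over DNA would give a ratio near 1. In the other libraries that ratio was 0.932 to 1.07, so it does not set replicate 5 apart. At the receptor rate 4 genes of the Y chromosome would have had 86.0 counts in replicate 5 and had 4. Replicate 6 had 2 against 29.3. If the background is DNA, such shortfalls would need female cells, unless reads of Y genes were lost in alignment or counting, which is not stated. Long brain-type genes of the X chromosome had 1.14 times the autosomal rate in replicate 5 and 1.23 times in replicate 6. They thus showed no shortfall, but the ratio was higher still in replicates 1 to 4. For the Y genes, replicates 1 to 4 had 6, 2, 3 and 13 counts against 7.03, 7.22, 10.2 and 13.9. Y genes have fewer copies per cell in male DNA than autosomal genes, so these expectations are too high for male cells. RNA of the Y genes would add counts, so replicates 1 to 4 do not tell the source. No biological explanation was tested, since the design gives no group to set against it.

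Cell-cycle genes were higher in set B, and the proliferation list had 64 to 102 counts per library in set A and 227 to 310 in set B. Background reads over gene spans are argued against, since after background subtraction the list was 4.75 times higher in set B per count outside ribosomal RNA and the sets did not overlap. Islet cells in replicates 4 and 6 stay open, because the value against them as the whole source comes from 1 library, replicate 5, whose hormone reads were at the level of set A and whose list had 3.35 times the highest set A library, with 93.8 of its 227 counts expected from background. More cycling cells in set B stay open as a hypothesis, since a second list of 28 mitosis genes, none in the fixed list, was 4.90 times higher in set B after subtraction, although in replicate 5 it had 444 counts against 367 expected from background. The meaning of the sets is not given, so a difference between animals, days or sorts cannot be separated from this one, and mesothelial cells were not tested as a source, although the mesothelial gene Msln averaged 1.33 counts in set A and 18.7 in set B while Upk3b had 16 counts in replicate 5 and 0 or 1 elsewhere.

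Hormone reads of Ins1, Ins2 and Gcg were 4262 and 9403 counts in replicates 4 and 6 and 42 to 203 in the other libraries, in cells sorted for GFP, a gate that may pass islet cells if they carry the reporter, which the genotype label does not name. Reads misassigned over the long Ins2 span are argued against by Ins1, on another chromosome, whose lower count of those replicates was 11.9 times the highest other library. Islet cells or their RNA stay open, since 17 islet genes other than hormones, 6 of them in a fixed list, had in the lower of those replicates 1.58 times the background-subtracted CPM outside ribosomal RNA of the highest other library, short of the 2 times set for a clear excess. These were 249 CPM in replicate 4 and 312 in replicate 6, against 122 to 158 in the others, and the hormone genes themselves reached 1523 and 3249 subtracted CPM, against 11.3 to 45.5 elsewhere. The summed list mixes members that moved differently. Without replicate 5, in a fit chosen after the values were seen, 6 of its members were tested. Their median log2 difference, set B over set A, was 3.13 and 4 were called higher by edgeR. Cpe (-0.03) and Ptprn2 (0.19) were not called. Apart from islet cells as a source of reads, no biological explanation was tested, since all libraries belong to 1 group.

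Of the 10 splits of the libraries into 3 and 3, 1 called as many genes as the split by name, which called 1 while the highest other called 0. For gene lists 6 of the 10 splits called as many lists, with 6 for the split by name and 9 for the highest other, which put replicates 1, 3 and 5 together. The 10 splits are too few for a share under 0.05.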

How the results depend on the processing

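The settings named here as gene span lengths, ribosomal RNA left out, low-background genes, background subtraction, the Rpl and Rps list without S6 kinase genes, and the limma test were chosen after the data were seen. No paired analysis was possible because the labels hold 1 group and no numbers that pair samples across groups. Of the results that answer a comparison and carry a p-value, 54 kept their direction and side of the threshold, 42 passed the threshold only under the alternative and 6 reversed. Of those 54 values 17 still moved by over 1.5 times. Of the counts, which have no threshold, 115 stayed within 1.5 times and 47 moved further. The 60 differences of list pairs without single replicates were not tested and lay within 1 SD. Among single genes and lists with a p-value 127 kept direction and side, 16 of them with a value moved by over 1.5 times, 39 became stronger, 24 weaker and 4 reversed, and 48 untested differences without single replicates lay within 1 SD. Where a cause is not given, the cause was not tested.

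Genes detected in every library were 811 at a TPM of 5, 6220 when 3 of 6 libraries sufficed and 1140 by gene span lengths, against 3762. List pairs past the exact or limma test numbered 7 with CPM, 7 with members at 1 TPM or more, 8 with medians, 7 by span lengths, 7 with ribosomal RNA left out and 8 with limma, against 0. An adjusted p just above the threshold, 0.052, decided the 0, because the smallest p is fixed by the design and the adjustment depends on how many pairs reach it.

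In the order CPM, members at 1 TPM or more, medians, span lengths and ribosomal RNA left out, enzymes minus ER gave 3.99, 6.21, 6.77, 4.66 and 5.11, acinar transcription factors minus ductal 1.80, 1.35, 2.0, 1.75 and 1.72, acinar minus endoderm transcription factors 3.31, 1.68, 3.05, 2.44 and 3.02, and immediate early minus proliferation 1.87, 1.71, 2.15, 1.98 and 2.11. With a pseudocount of 0.1 no pair passed, but differences grew, to 4.07 for acinar minus endoderm transcription factors, 2.99 for immediate early minus proliferation, 2.0 for ductal minus endocrine, 0.87 for myeloid minus lymphoid, 0.34 for fibroblast minus endothelial and 0.20 for ISWI minus BAF. With limma the enzyme, the 2 acinar transcription factor and the immediate early pairs were as reported, 5.14, 1.58, 2.67 and 1.86, and so were receptors minus ductal at 0.32, ductal minus endocrine at 0.87, ductal minus metaplasia at -0.20 and myeloid minus lymphoid at 0.28. Past the threshold were also receptors minus ductal with members at 1 TPM or more (0.70), ductal minus endocrine with CPM (1.59), medians (1.35) and ribosomal RNA left out (1.11), myeloid minus lymphoid with CPM (0.34), medians (0.20) and ribosomal RNA left out (0.38), fibroblast minus endothelial by span lengths (0.17), and ISWI minus BAF with CPM (0.34), medians (0.22) and span lengths (0.15). Ductal minus metaplasia passed with members at 1 TPM or more (-0.82), span lengths (-0.33) and ribosomal RNA left out (-0.13), but reversed with CPM (0.10), a pseudocount of 0.1 (0.089) and medians (0.47), where it passed in the opposite direction (adjusted exact p = 0.039). Members at 1 TPM or more reversed ductal minus endocrine (-0.42) and ISWI minus BAF (-0.22), the latter past the threshold in the opposite direction (adjusted exact p = 0.045), and medians reversed fibroblast minus endothelial (-0.057).

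ATPases past the test above Smarca5 numbered 1 by span lengths and 2 with limma, and below it 26 and 17. On average 12 were above it with CPM and 1 by span lengths, 5 to 8 when single replicates were left out (8 without replicate 6), and 9 were below it among members at 1 TPM or more, where fewer genes are compared. Klf genes past the test above Klf5 numbered 6 with CPM, 5 with members at 1 TPM or more and 5 with limma, and below it 7 with CPM and 5 with limma, while the 0 below it among members at 1 TPM or more was fixed by the filter, since Klf5 itself averages 0.784 TPM. Gene span lengths reversed Smarca4 minus Smarca5 (-0.030) and Klf12 minus Klf5 (-0.36), and lowered Klf13 minus Klf5 to 0.31 and Klf9 minus Klf5 to 1.37. Smarca1 minus Smarca5 was -1.44 with CPM and -1.59 with a pseudocount of 0.1.

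Between the sets, genes higher and lower in set B were 794 and 227 with DESeq2, 790 and 203 with no filter, 4 and 35 at a mean count of 50 or more, and 123 and 150 among low-background genes. Leaving out single replicates gave 0 to 1656 higher and 0 to 561 lower, the largest without replicate 4 (1656 and 561) and without replicate 5 (366 and 369). Lists higher in set B were 0 at a mean count of 50 or more and 0 with an estimated correlation, and 1 to 3 without single replicates (1 without replicate 6). Lists lower in set B were 1 at a mean count of 50 or more, 0 with an estimated correlation, 1 among low-background genes, 1 after background subtraction, and 1 to 5 without single replicates (1 without replicate 5). The list of Rpl and Rps genes reversed among low-background genes (0.022, adjusted p = 0.65 by limma's camera) and after background subtraction (0.24, adjusted p = 0.015 by camera), and over its alternatives the adjusted p ranged from 4.7e-05 to 0.72. Without S6 kinase genes and Rps19bp1 it stayed lower, at -0.51. After background subtraction the ER list was at 0.0024 and the immediate early list at -0.11, neither of them past the threshold. The enzyme list kept its direction in all 12 alternatives, from -1.68 to -0.59, and the proliferation list in all 11, from 1.08 to 1.93, while a mean count of 50 or more left it too few genes for a value.

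Depth limits the low genes most. Smarca5 had 21 to 51 counts and Klf5 9 to 16, and a count of 0 allows up to 0.642 CPM in the smallest library.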

Other observations

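Both tests of the ATF4 targets in this part concern a list written after the genes in question were seen, and of these the test among low-background genes was chosen before its result was seen. Fgf21, Nupr1, Atf5 and Cth were lower in set B without replicate 5. No fixed list covers these genes as a group, and without replicate 5 the ER list (-0.28, adjusted p = 0.11 by limma's camera) and the immediate early list (-0.20, 0.31) lost their calls. A hypothesis is that targets of ATF4, the transcription factor of the integrated stress response, may have been expressed less in set B. In a list of 30 further ATF4 targets, 4 of them in a fixed list, the median log2 difference was -0.91 over 25 tested genes and 24 of these lay lower, the exception being Slc7a11 (1.51, and 0.96 with an edgeR adjusted p of 0.017 without replicate 5), with a fry p of 0.021 but a p of 0.14 by camera with an estimated correlation. Background reads that lower the shares of expressed genes are argued against as the whole cause, since among 3659 low-background genes the median was -0.53, below all of 10000 random lists matched on expression, whose median was -0.03, and 22 of 24 members lay lower with 4 called by edgeR. The random genes were drawn independently, so the rank ignores how ATF4 targets vary together. The acinar enzyme list also lay lower among low-background genes, so the rank does not set ATF4 targets apart from a wider fall. The difference in the share of ribosomal RNA and the unknown meaning of the sets stay open.

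Hemoglobin transcripts were found almost only in replicate 6, apart from 2 counts each in replicates 2 and 4, where Hbb-bs had 53 counts, Hba-a1 27 and Hba-a2 15. Long brain-type genes of the X chromosome had 1.14 times the rate of the autosomal ones in replicate 5 and 1.23 to 1.51 times in the other libraries.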
